A study of Mus musculus with 26 samples.

How the data were processed

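Nascent RNA was measured by precision run-on sequencing (PRO-seq) in forebrain tissue, which the labels' protocols describe as cortex with hippocampus, of C57BL/6 mice aged 8 to 12 weeks. The 26 samples formed 3 experiments, and the series design gives each library as a separate mouse. These were 5 Mecp2 knockout (KO) mice with 5 wild-type controls, 5 mice with the R306C change of MeCP2 with 5 controls, and 3 Dnmt3a conditional knockout (cKO) mice with 3 controls, with littermates as controls in each case. The p-values of tests on single genes and of permutations of libraries therefore measure the spread between these mice. Fisher's exact test takes genes as its units, and genes are not independent, so its p-values do not measure that spread. The labels gave female for Dnmt3a control 2 and Dnmt3a cKO 1 and male for the other 24 mice. They gave an age of 8 weeks in the Mecp2 KO experiment and of 8 to 12 weeks in the R306C and Dnmt3a cKO experiments. Age may therefore differ between experiments that are compared or fitted together.

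The deposited counts were whole-number read counts per gene and library in 6 tables, 1 for the transcription start site (TSS) window and 1 for the gene body in each experiment. Per the file names, they cover genes of over 3000 bp. The submitters' processing notes name Bowtie2 2.2.9, bedtools 2.26.0 and the genome build mm10, without a role for either tool. The limits of the windows, the use of strand and any scaling of the libraries are not stated. Counts of TSS and gene body together differed by a coefficient of variation of only 1.75% between the libraries of the Mecp2 KO experiment, 2.87% in the R306C and 1.96% in the Dnmt3a cKO experiment. No library or gene was left out before the low count filter.

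Gene spans came from the RefSeq annotation of the mouse genome, matched for 18670 of 19374 genes by symbol and for 651 by synonym. Genes with a span of over 100 kb numbered 2479, and 6 matched genes had a span under 3000 bp. TSS counts were identical in every library for 70 genes, and gene body counts for 2, so that such genes (Pakap and Palm2 among them) cannot be told apart.

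Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10, TMM factors and the quasi-likelihood F test of mutant against control in each experiment and window. Adjusted p denotes the Benjamini-Hochberg value over the genes tested, with a threshold of 0.05, and every test was two-sided. The change of the gene body to TSS ratio was the edgeR interaction of window with genotype, with the mouse as a block. CPM denotes counts-per-million values with TMM factors, computed here from the deposited counts, and log2 CPM used a prior count of 2. The long gene score of a library was the mean log2 CPM of the genes over 100 kb minus that of the other tested genes. It was compared by exact permutation of the library labels, whose smallest possible p is 0.00794 with 5 mice per group and 0.1 with 3.

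26 gene lists were fixed from general knowledge: markers of astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors, vascular cells, choroid plexus, excitatory neurons, inhibitory neurons, striatum, thalamus, hippocampus and proliferating or newborn neurons; axon guidance genes, cadherins and protocadherins, very long neuronal genes, voltage-gated channels, GABA receptors, glutamate receptors, immediate early genes, imprinted genes, DNA methylation machinery, heat shock genes, oxidative phosphorylation genes, ribosomal protein genes, Hox genes and widely discussed MeCP2 targets. Each list, and the genes over 100 kb, was tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of an experiment and window. The same test with an estimated correlation, and fry, served as checks.

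Genes selected in the gene body of 1 experiment were scored in the libraries of another (mean log2 CPM of the higher minus the lower genes), with exact permutation. The selection was an adjusted p under 0.05, or under 0.1 where fewer than 20 genes passed in a direction. It found no gene in the Mecp2 KO and R306C experiments, for which an unadjusted p under 0.01, fixed at the start only as an alternative, was used instead once this was seen. Fold changes were correlated across genes and compared with all 252 arrangements of the labels of a 5 against 5 experiment. Genes are not independent replicates in such a correlation. Differences of effects between experiments were edgeR contrasts over all 26 libraries.

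The replicate numbers in the titles were tested as pairs through the correlation of the deviations from the group means. The lowest correlation of a same-numbered pair was 0.22 (gene body) and 0.26 (TSS) in the Mecp2 KO experiment and 0.35 and 0.41 in the R306C experiment, each over the limit of 0.1, so the numbers were taken to pair those samples. In the Mecp2 KO experiment, however, only 3 (gene body) and 2 (TSS) of 10 libraries correlated best with the library of their own number, against 9 and 9 of 10 in the R306C experiment. The labels do not say what a number marks. A fit with the number as a block is the blocked fit, and the text gives its value where it changes a call.

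The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Mecp2 and Dnmt3a in every experiment, the 10 higher and 10 lower genes in the gene body and the 5 higher and 5 lower in the TSS window with the largest fold change among genes with an adjusted p under 0.05, a mean count of at least 20 and the same sign in every mutant library. Where fewer than 5 passed, the genes with the lowest p filled the list up to 5. From each list it took the 4 members with the lowest p, and it took the 5 genes with the lowest p for the ratio. Irak1 was followed in every experiment after its values were seen.

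Added after the data were seen were a joint edgeR fit of both Mecp2 mutants with a block per experiment and replicate number (10 pairs), its gene lists and long gene score, the log2 ratio of TSS to gene body totals as a covariate, the block in the ratio fit, differences of effects in TSS counts, selection with the block, and the omission of the R306C pair numbered 2. The alternatives fixed at the start were DESeq2 1.42.0 (size factors, and its Wald test), no low count filter, a mean of at least 50 counts, sex as a covariate, limma on the difference of log2 CPM for the ratio, medians, length limits of 60 and 200 kb, shorter genes matched by expression, and the omission of each library.

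The TSS and gene body totals were 36.4 to 38.4 M (mega) counts per library in the Mecp2 KO, 26.8 to 29.7 M in the R306C and 18.3 to 19.4 M in the Dnmt3a cKO experiment. The chi-square per gene between pairs of replicates, with counting error alone as the reference, was 2.02 at the lowest and 142 at the highest. The tests were tested on simulated data with 200 changed genes per comparison. The simulated counts were drawn independently for each gene, without shifts shared across genes other than the pair means of the joint design. The real libraries can hold such shifts, so the rates below describe the simulated data only. Of genes changed 2-fold, 68% (gene body) and 78% (TSS) were recovered in the Mecp2 KO design, 64% and 84% in the R306C design, 50% and 86% in the Dnmt3a cKO design and 100% in the joint design. Of genes changed 1.25-fold, 2% and 18%, 0% and 4%, 2% and 0%, and 46% and 76% were recovered in the same order. False calls were 2 of 94 (gene body) and 5 of 127 (TSS) in the Mecp2 KO design, 8 of 94 and 7 of 127 in the R306C design, 10 of 88 and 10 of 112 in the Dnmt3a cKO design, and 8 of 175 and 19 of 201 in the joint design, so that in some designs they exceeded the nominal 5%.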

Results

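PRO-seq counts of nascent RNA were available for the forebrain of 26 mice in 3 experiments, each with its own wild-type littermates. The mutants were 5 Mecp2 knockout (KO) males, 5 males with the R306C change in the part of MeCP2 that binds the NCoR corepressor, and 3 Dnmt3a conditional knockout (cKO) mice, with 5, 5 and 3 controls. MeCP2 binds methylated DNA, and Dnmt3a is a DNA methyltransferase. Counts covered 19374 genes in a TSS window and a gene body window. Gene body totals were 12.5 to 20.6 M (mega) counts in the Mecp2 KO, 6.79 to 14.0 M in the R306C and 5.72 to 8.58 M in the Dnmt3a cKO experiment. The share of counts in the TSS window ran from 43.4% to 77.1% over the libraries, and the highest shares were those of R306C control 2 (77.1%) and R306C mutant 2 (72.4%). The mean share was 55.8 ± 8.84% in controls and 61.3 ± 6.18% in Mecp2 KO mice (SD, n = 5 per group, exact permutation p = 0.294). It was 60.4 ± 10.6% and 62.1 ± 6.66% in the R306C experiment (SD, n = 5 per group, exact permutation p = 0.778). In the Dnmt3a cKO experiment it was 57.2 ± 5.48% and 65.2 ± 5.35% (SD, n = 3 per group, exact permutation p = 0.2, smallest possible 0.1). Adjusted over these 3 tests, the p-values were 0.440, 0.778 and 0.440 (exact permutation). Xist, which is transcribed from the inactive X chromosome, had 27.0 and 27.8 counts per M counts of the library (without TMM factors) at the TSS in the 2 mice labelled female and at most 0.313 in the other 24. Ddx3y on the Y chromosome had at most 0.0811 in those 2 and at least 22.5 in the rest, on the same scale.

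**Figure D1:**
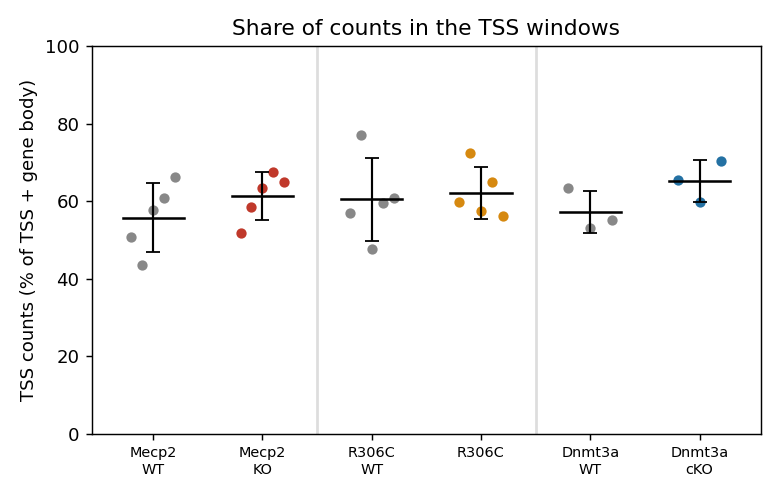
Share of counts in the TSS window (vertical axis, percent of TSS plus gene body counts) of each library (points) in the 6 groups (horizontal axis), with the mean and SD as bars. Shares ran from 43.4% to 77.1%, and the SD within groups (6.18 to 10.6 points) exceeded the difference between groups in the Mecp2 KO and R306C experiments, but not in the Dnmt3a cKO experiment.

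The targeted genes were called in no experiment. Mecp2 TSS counts were 87.1 ± 1.57 CPM in controls and 90.5 ± 3.55 CPM in Mecp2 KO mice (SD, n = 5; log2 fold change 0.05 ± 0.05 SE), and gene body counts were 86.1 ± 10.2 and 76.7 ± 14.6 CPM (log2 fold change −0.17 ± 0.14). In R306C mice the log2 fold change of Mecp2 was −0.04 ± 0.08 at the TSS and 0.01 ± 0.16 in the gene body. In Dnmt3a cKO mice, Dnmt3a had 242 ± 47.1 CPM in controls and 196 ± 9.82 CPM in mutants at the TSS (SD, n = 3; log2 fold change −0.30 ± 0.15, edgeR adjusted p = 0.644). Its gene body counts were 292 ± 17.3 and 309 ± 26.7 CPM (log2 fold change 0.08 ± 0.12). Mecp2 in these mice had −0.23 ± 0.12 in the gene body and 0.08 ± 0.11 at the TSS. Dnmt3a had 0.00 ± 0.09 and −0.01 ± 0.14 in Mecp2 KO mice and −0.11 ± 0.14 and 0.00 ± 0.10 in R306C mice (gene body and TSS). The deleted parts of both genes are not given and R306C is a single amino acid change, so that these counts are no check of genotype.

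In Mecp2 KO forebrain, 2 genes fell at the TSS and none rose. Irak1, a kinase of interleukin-1 receptor signalling that lies next to Mecp2 on the X chromosome, fell 3.63-fold, from 50.9 ± 3.71 to 14.0 ± 1.75 CPM (SD, n = 5; log2 fold change −1.86 ± 0.10, adjusted p = 6.72e-06). Adgrg1, an adhesion G protein-coupled receptor of neural progenitors and glia, fell 2.72-fold, from 4.66 ± 0.216 to 1.71 ± 0.227 CPM (log2 fold change −1.44 ± 0.17, adjusted p = 0.0154). In the gene body, Irak1 had a log2 fold change of −0.54 ± 0.19 (adjusted p = 0.877). With the block, Hist1h2bq, a histone gene (log2 fold change −0.46 ± 0.07), and Sspn, a partner of the dystrophin complex (−0.75 ± 0.11), fell as well, which made 4 genes; both were chosen after their values were seen. The TSS genes with the lowest p among those that did not pass (mean of at least 20 counts) included Kcns1 (0.62), a potassium channel subunit, Per2 (0.47), a circadian regulator, and Efna5 (0.44), an axon guidance ligand, with Ifi27l2a (−0.95), Cacnb3 (−0.55) and Haglr (−1.75) on the lower side (adjusted p = 0.695 to 0.699).

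The tests covered 15275 genes at the TSS, of which 835 had an unadjusted p under 0.05, and DESeq2 called 15 higher and 11 lower genes. Irak1 passed in all 10 omissions of a library. Adgrg1 no longer passed without any 1 of the 5 controls or without KO 1, KO 2 or KO 4 (edgeR adjusted p = 0.0511 to 0.109), and it passed without KO 3 (0.0409) or KO 5 (0.0444).

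**Figure D2:**
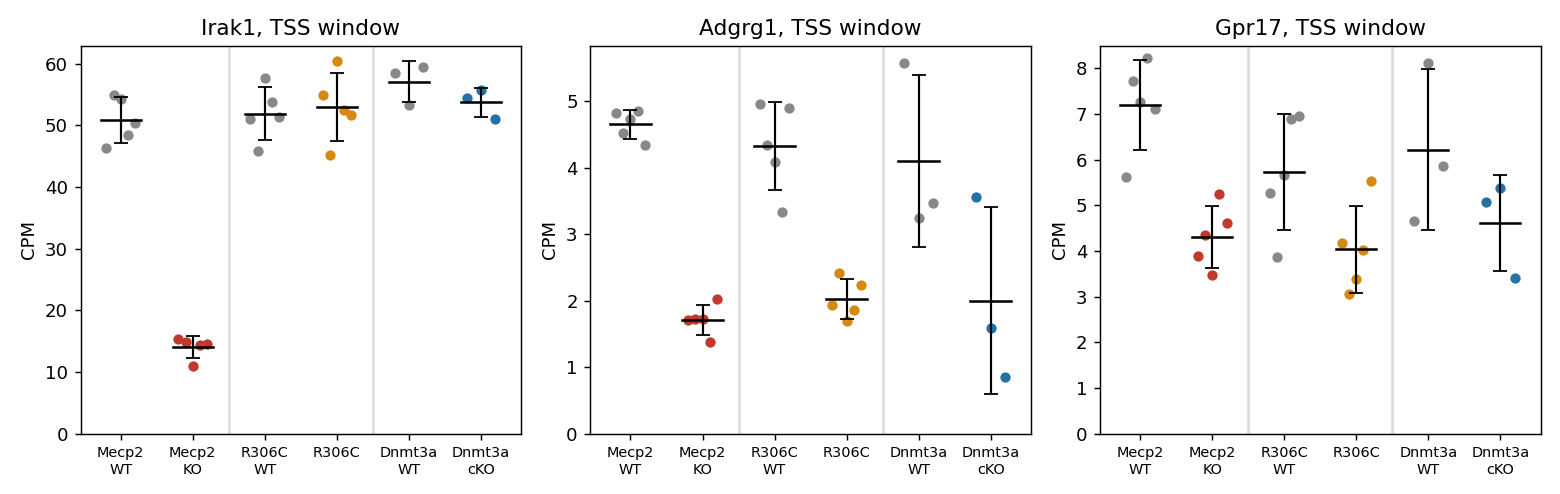
TSS counts in CPM (vertical axes) of Irak1, Adgrg1 and Gpr17 in each library (points) of the 6 groups (horizontal axes), with the mean and SD as bars. Irak1 fell in the Mecp2 KO (50.9 to 14.0 CPM), while Adgrg1 had 4.66 and 1.71 CPM there and 4.33 and 2.03 CPM in the R306C experiment.

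In gene bodies of Mecp2 KO mice, edgeR called 0 of 17448 genes, while 953 had an unadjusted p under 0.05 and DESeq2 called 72 higher and 1 lower. Of the 72 higher genes, 68.1% spanned over 100 kb. Among the genes with the lowest p were Fabp4, a fatty acid binding protein (2.34 ± 0.38, 0.609 to 3.05 CPM), Esrrg, a nuclear receptor (0.51 ± 0.09, 219 to 312 CPM), Tenm3, a teneurin of synaptic wiring (0.49), and Abca8a, a lipid transporter (−0.94 ± 0.16, 12.4 to 6.46 CPM), as log2 fold change with SE and adjusted p = 0.427 to 0.669 by edgeR. Without KO 1, 1 gene was called higher. The gene body to TSS ratio changed in 0 of 15047 genes by edgeR (839 with an unadjusted p under 0.05, and 0 by limma). With the block it rose for 2 genes, Adgrg1 (log2 1.53 ± 0.16) and Irak1 (1.30 ± 0.15).

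The TSS counts of genes that guide axons and of long genes rose as groups in Mecp2 KO mice. Of 35 axon guidance genes 27 had a positive log2 fold change (median 0.13, camera adjusted p = 1.13e-05), with Efna5 (0.44 ± 0.09) and the receptor Robo1 (0.34 ± 0.09) higher when adjusted over the list alone and none over all genes. Of 2249 genes over 100 kb, 1471 were positive (median 0.05, camera adjusted p = 0.000101). These were the 2 of 11 called lists that held with an estimated correlation (adjusted p = 0.0310 and 0.0237). The other 9 calls did not. Very long neuronal genes (38 of 40 positive, median 0.14) had an adjusted p of 5.38e-06, and 0.242 with an estimated correlation. All 24 excitatory neuron markers were positive (median 0.13, adjusted p = 0.00023, and 0.0910 with an estimated correlation).

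Markers of microglia and of the oligodendrocyte lineage lay lower at the TSS in the same mice, while astrocyte markers were not called (median 0.02, camera adjusted p = 0.137). All 18 microglia markers were negative, among them Cx3cr1 (−0.47) and Csf1r (−0.35), receptors that mark these cells (median −0.30, camera adjusted p = 7.75e-07, and 0.181 with an estimated correlation). Of 20 oligodendrocyte markers 18 were negative, such as the myelin gene Plp1 (−0.61; median −0.27, adjusted p = 5.38e-06, and 0.284 with an estimated correlation). Of 10 oligodendrocyte precursor markers 9 were negative (median −0.37, adjusted p = 0.000103, and 0.206 with an estimated correlation), and Gpr17, a receptor of maturing precursors, fell when adjusted over the list alone (−0.73 ± 0.17). Cadherins (median 0.12, 0.00978 and 0.374), immediate early genes (0.10, 0.00951 and 0.206), proliferation markers (−0.09, 0.0190 and 0.206) and DNA methylation machinery (0.04, 0.0461 and 0.181) made up the calls, with the adjusted p given for the preset and then the estimated correlation.

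In gene bodies of the Mecp2 KO, 13 lists were called and none held with an estimated correlation (lowest adjusted p = 0.624). Excitatory neuron markers (23 of 24 positive, median 0.18, camera adjusted p = 9.79e-05), imprinted genes (32 of 36 positive, median 0.14, 0.000363), axon guidance genes (27 of 36, 0.15, 0.00178), striatal markers (11 of 13, 0.15, 0.00178) and immediate early genes (23 of 25, 0.17, 0.00249) lay higher. Oligodendrocyte markers (19 of 20 negative, median −0.16, 0.00249), precursor markers (10 of 11, −0.25, 0.00854), microglia markers (16 of 18, −0.22, 0.0195) and heat shock genes (12 of 14, −0.17, 0.0285) lay lower. The others were voltage-gated channels (median 0.09, 0.0166), genes over 100 kb (0.03, 0.0237), choroid plexus markers (0.18, 0.0305) and vascular markers (−0.10, 0.0368). With the block, the calls of the genes over 100 kb (adjusted p = 0.0889) and of vascular markers (0.0519) ended. No member was called over all genes. Adjusted over the list alone, Cdh4 (0.58) and Cdh6 (0.42) of the cadherins, the striatal signalling gene Ppp1r1b (0.41), and Ttr (0.64) and Clic6 (0.47) of the choroid plexus rose, and the GABA receptor gene Gabrg1 fell (−0.45).

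In R306C forebrain, 11 TSS genes were called with the block and 0 without it. Of these, 10 fell: Ccnd1, the cell cycle gene of cyclin D1 (log2 fold change −0.56 ± 0.06, blocked adjusted p = 0.00221), Fgf10, a growth factor (−1.01 ± 0.13, 0.0142), the calcium and sodium channel genes Cacnb3 (−0.56) and Scn9a (−0.76), the secreted glycoprotein gene Stc1 (−0.51, 0.0292), Fam222a (−0.41), Adgrg1 (−1.08 ± 0.17, 0.0328), AW551984 (−1.17), the carbonic anhydrase gene Car4 (−0.43) and the splicing factor gene Srsf7 (−0.48). Kcns1 rose (0.49 ± 0.08, 0.0491), from 12.9 to 18.1 CPM. Ccnd1, Cacnb3, Scn9a, Fam222a, Car4 and Srsf7 were chosen after their values were seen. Srsf7 can vary widely within a group: among Dnmt3a cKO mice it had 32360 TSS counts in cKO 3 and at most 10259 in cKO 1. Adgrg1 went from 4.33 ± 0.666 to 2.03 ± 0.296 CPM and Fgf10 from 7.23 ± 0.966 to 3.60 ± 0.612 CPM (SD, n = 5). Without the block, edgeR called 0 of 14943 genes (229 with an unadjusted p under 0.05, of which 192 were negative) and DESeq2 called 1 higher and 6 lower. The adjusted p of Adgrg1 and Fgf10 was then 0.459.

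In R306C gene bodies, edgeR called 0 of 17060 genes with or without the block (125 without it at an unadjusted p under 0.05, and 0 by DESeq2). Abca8a (−0.73 ± 0.15), Stc1 (−0.84), Ptgfrn (0.43) and Bmper (0.38), a modulator of BMP signalling, were among the genes with the lowest p (log2 fold change). The gene body to TSS ratio changed in 0 of 14636 genes by edgeR (61 at an unadjusted p under 0.05, and 0 by limma).

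Oligodendrocyte precursor markers fell as a group at the TSS of R306C mice: all 10 were negative (median −0.34, camera adjusted p = 5.53e-06, and 0.0164 with an estimated correlation). Neu4 (−0.50 ± 0.19), Gpr17 (−0.51 ± 0.21), the growth factor receptor gene Pdgfra (−0.39) and the transcription factor gene Olig2 (−0.25) were among them, and none passed alone. Vascular markers were the other call (16 of 19 negative, median −0.17, adjusted p = 0.0206, and 0.811 with an estimated correlation). Adjusted over the list alone, Gabrg1 fell (−0.48). In gene bodies, 8 lists were called and none held with an estimated correlation (lowest adjusted p = 0.927). Precursor markers (median −0.26, 0.000321), vascular markers (−0.15, 0.000858) and microglia markers (−0.11, 0.0161) lay lower. Excitatory neuron markers (0.06, 0.0121), axon guidance genes (0.08, 0.0161), very long neuronal genes (36 of 40 positive, 0.07, 0.0223), ribosomal protein genes (0.07, 0.0283) and genes over 100 kb (0.02, 0.0363) lay higher. With the block, cadherins (adjusted p = 0.0223) and imprinted genes (0.0336) were called higher as well.

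In the fit of both Mecp2 mutants together, added after the data were seen, 36 genes rose and 22 fell in gene bodies, and 108 rose and 193 fell at the TSS, with 10 mice per group. The genes that rose were long: 21 of the 36 gene body calls spanned over 100 kb (58.3%, against 14.2% of the genes tested, Fisher's exact p = 9.26e-10), as did 43 of the 108 TSS calls (39.8% against 14.7%, Fisher's exact p = 1.53e-10). Fisher's exact test takes genes as independent units, which they are not, so its p-values do not measure the spread between mice. Genes that fell were not longer in the gene body (3 of 22, 13.6%, Fisher's exact p = 1) and were shorter at the TSS (13 of 192 with a span, 6.77%, Fisher's exact p = 0.000955). Long genes that rose in the gene body included Efna5 (log2 fold change 0.51 ± 0.06, 155 to 221 CPM, 278 kb), the cell adhesion genes Sdk1 (0.45 ± 0.06, 974 kb) and Cdh4 (0.46 ± 0.08, 457 kb), Bmper (0.47 ± 0.06, 262 kb) and Trabd2b (0.41 ± 0.08). Shorter ones were Fabp4 (1.97 ± 0.22), Mroh4 (0.77), Gm6498 (0.56), Gm11549 (0.50), the growth factor gene Fgf5 (0.54 ± 0.09), Ptgfrn (0.48 ± 0.07) and Tbr1, a transcription factor of deep-layer cortical neurons (0.29 ± 0.06).

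Of the lower gene body calls with a mean of at least 20 counts and the same sign in every mutant library, the 10 with the largest fold change were Abca8a (log2 fold change −0.82 ± 0.10, 14.2 to 8.11 CPM, adjusted p = 0.00139), the glycoprotein hormones Stc1 (−0.74 ± 0.09) and Stc2 (−0.67 ± 0.14), Gm10406 (−0.72), the betaine and GABA transporter Slc6a12 (−0.57 ± 0.08), Fgf10 (−0.51 ± 0.07), Efemp1 (−0.51), the kappa opioid receptor gene Oprk1 (−0.49 ± 0.10), Igfbp2 (−0.39) and Ptgs1 (−0.37). At the TSS, Adgrg1 fell 2.41-fold (−1.27 ± 0.12, 4.48 ± 0.487 to 1.87 ± 0.308 CPM, SD, n = 10, adjusted p = 5.06e-05), as did Haglr (−1.22), AW551984 (−1.12), Nt5dc2 (−1.07) and Pth2r (−0.92). Higher at the TSS were 3100003L05Rik (0.80), Mypn (0.65), Kcns1 (0.56 ± 0.06, 12.0 to 17.6 CPM), the BMP receptor gene Bmpr1b (0.55 ± 0.11) and Igf2bp2 (0.55). Irak1 had a log2 fold change of −0.87 ± 0.23 and did not pass (adjusted p = 0.0543).

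**Figure D3:**
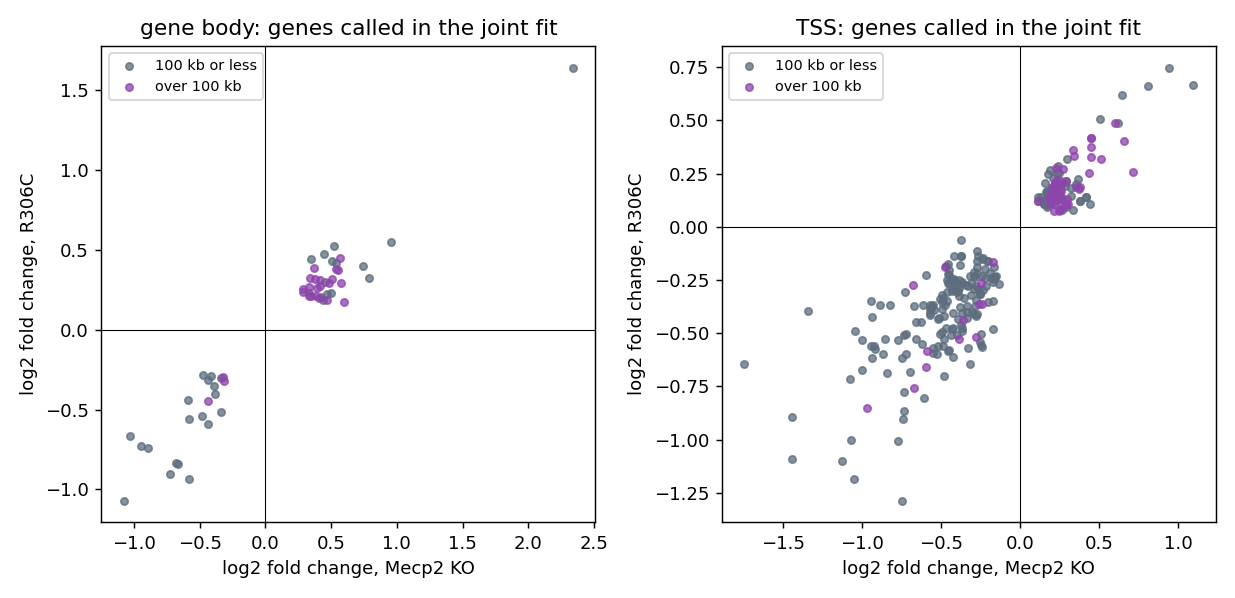
Log2 fold change in the R306C experiment against that in the Mecp2 KO (axes) of the genes called in the joint fit (points), for gene bodies on the left and the TSS on the right, with genes over 100 kb marked apart from shorter ones. The genes were chosen on the same mice, so that their common direction follows from the choice, and 58.3% of the higher gene body calls but 13.6% of the lower ones span over 100 kb.

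The joint counts rested on the pairing. Without the block, 3 higher and 1 lower genes were called in gene bodies and 5 and 15 at the TSS. DESeq2, with the block, called 148 and 71 in gene bodies and 216 and 270 at the TSS. With the TSS to gene body ratio as a covariate, 49 and 85 were called in gene bodies and 26 and 78 at the TSS. That covariate fit had no block, so the fit without the block is its reference. Without the R306C pair numbered 2, gene body calls were 181 and 62, and 50.8% of the 181 spanned over 100 kb. With the block, omitting either library of a pair takes that pair out of the comparison, so both omissions test nearly the same thing. Higher gene body calls numbered 119 without R306C control 2, 136 without R306C mutant 2 and 11 to 21 without any other library except Mecp2 control 3 (37), KO 3 (37) and R306C mutant 5 (24). Lower gene body calls numbered 58 and 56 without those R306C libraries numbered 2, 18 and 15 without control 3 and KO 3, and 5 to 12 without any other. Higher TSS calls numbered 74 to 101 without control 3, KO 3, R306C control 2, R306C mutant 2 or R306C mutant 3, and 25 (without control 2 or KO 2 of the Mecp2 experiment) to 69 without any other. Lower TSS calls numbered 139 to 172 without control 3, KO 3, or the R306C libraries numbered 2 and 3, and 72 to 123 without any other.

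Oligodendrocyte precursor markers fell in both mutants together. At the TSS, 4 of 10 fell over all genes: Gpr17 (log2 fold change −0.62 ± 0.10, 6.45 to 4.18 CPM, adjusted p = 0.00417), the sialidase gene Neu4 (−0.50 ± 0.11), the proteoglycan gene Vcan (−0.36 ± 0.08) and Olig2 (−0.37 ± 0.09), and 7 fell when adjusted over the list alone. The list had 9 of 10 members negative (median −0.36, camera adjusted p = 3.9e-07, and 0.00585 with an estimated correlation), the only one of 8 TSS calls to hold with it. The other 7 were microglia markers (all 18 negative, median −0.19, 6.88e-05 and 0.541), oligodendrocyte markers (18 of 20 negative, −0.19, 0.000281 and 0.571), very long neuronal genes (31 of 40 positive, 0.07, 0.0024 and 0.609), excitatory neuron markers (0.06, 0.00771 and 0.571), genes over 100 kb (0.02, 0.00771 and 0.541), axon guidance genes (0.07, 0.0170 and 0.571) and vascular markers (−0.10, 0.0424 and 0.609), with the adjusted p for the preset and then the estimated correlation. In gene bodies 12 lists were called and none held with an estimated correlation (lowest adjusted p = 0.201). Excitatory neuron markers (23 of 24 positive, 0.12, 4.18e-06 and 0.413), axon guidance genes (27 of 36 positive, 0.09, 3.59e-05 and 0.562; 1 rose over all genes, and 10 rose and 2 fell adjusted over the list alone) and imprinted genes (32 of 36 positive, 0.12, 5.3e-05 and 0.562) lay higher. Precursor markers (−0.25, 4.18e-06 and 0.370), microglia markers (−0.16, 1.44e-05 and 0.370) and vascular markers (−0.12, 0.000169 and 0.201) lay lower.

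Transcription of long genes, which the title names, was addressed with a score per library. The title also names highly methylated genes, which were not tested, since DNA methylation values per gene were not at hand. The score therefore takes all genes over 100 kb, whatever their methylation. At the TSS of Mecp2 KO mice the long gene score was 0.06 ± 0.03 against −0.01 ± 0.03 in controls (SD, n = 5 per group, difference 0.07 on the log2 scale, exact permutation p = 0.0159). Adjusted over the 9 scores of the 3 experiments the exact permutation p was 0.143, and with differences within pairs it was 0.0625, the smallest that 5 pairs allow. In R306C mice the difference at the TSS was 0.01 (exact permutation p = 0.373). Over all 10 pairs of both Mecp2 mutants it was 0.04 ± 0.04 (SD), higher in 8 of 10 pairs (exact sign flip permutation p = 0.0156, and 0.0469 adjusted over the 3 joint scores). The joint scores were added after the data were seen and reuse libraries of the 9 scores. No adjustment over both sets was made, so the adjusted value is a lenient one. Gene body scores differed by 0.02 in the Mecp2 KO (p = 0.786) and 0.03 in R306C mice (p = 0.643), and by 0.03 over the 10 pairs (p = 0.281), each by exact permutation. The difference of gene body and TSS was −0.04 in the KO, 0.02 in R306C mice and −0.01 over the pairs (exact permutation p = 0.698, 0.794 and 0.746).

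Along gene length, the TSS change in Mecp2 KO mice ran from −0.04 for genes under 10 kb to 0.10 for genes over 400 kb (log2, exact permutation p = 0.0794 and 0.0317). It was −0.01 for genes of 10 to 30 kb and 0.04 for genes of 100 to 200 kb (exact permutation p = 0.00794 for each, the smallest possible with n = 5). Over 400 kb the change was 0.03 in R306C mice (p = 0.333) and 0.14 in Dnmt3a cKO mice (p = 0.1, the smallest possible with 3 mice per group), both by exact permutation. None passed after adjustment over the 63 length bins (lowest 0.25, exact permutation). The bins were tested without pairs. In gene bodies over 400 kb the change was 0.06 in R306C mice, higher in 5 of 5 pairs (exact permutation p = 0.611). There it was 0.03 in the Mecp2 KO, higher in 4 of 5 pairs, and −0.03 in the Dnmt3a cKO. In the Dnmt3a cKO the long gene score differed by 0.06 at the TSS (p = 0.2), −0.01 in gene bodies (p = 0.4) and −0.05 for their difference (p = 0.2), by exact permutation. Against shorter genes matched by expression, the gene body score was −0.15 (exact permutation p = 0.1, the smallest possible) and the difference −0.31 (exact permutation p = 0.2).

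**Figure D4:**
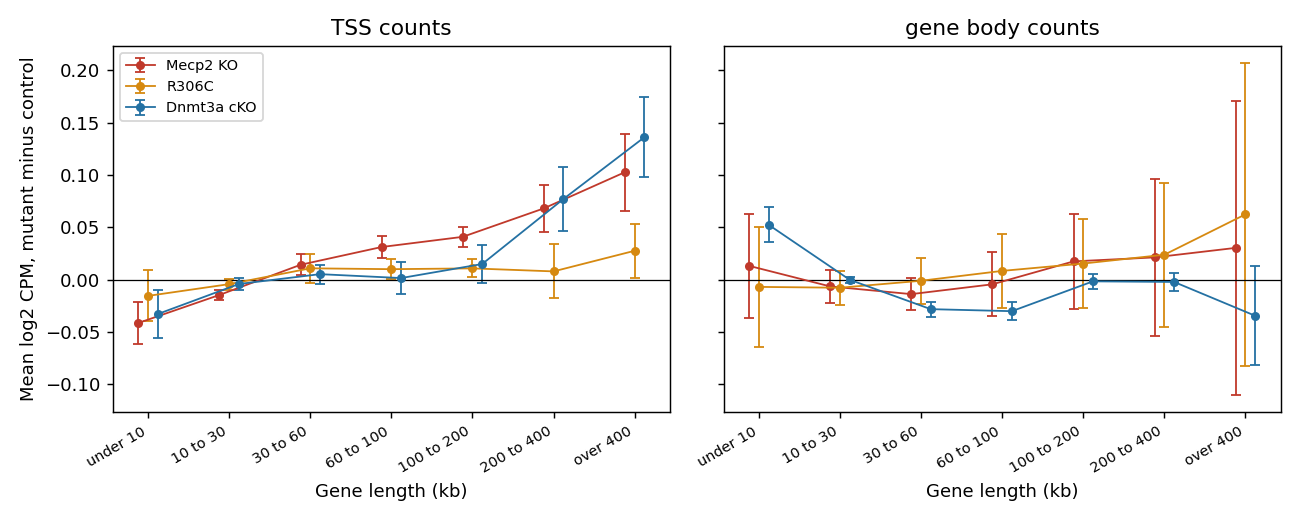
Mean change of log2 CPM, mutant minus control (vertical axes), in 7 bins of gene length (horizontal axes, kb) for the 3 experiments, with the TSS on the left and gene bodies on the right and the standard error of the difference as bars. At the TSS of the Mecp2 KO the change goes from −0.04 in genes under 10 kb to 0.10 in genes over 400 kb.

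In Dnmt3a cKO forebrain, 46 genes rose in the gene body and none fell. Ftcd, an enzyme of histidine breakdown, rose 6.41-fold, from 4.02 ± 1.76 to 25.5 ± 6.91 CPM (SD, n = 3; log2 fold change 2.68 ± 0.30, adjusted p = 0.0106). Dchs1, a protocadherin of tissue growth control, rose from 39.6 ± 2.72 to 157 ± 37.9 CPM (1.98 ± 0.18, adjusted p = 0.00659), and C530008M17Rik, at 216 kb, from 30.6 ± 2.13 to 116 ± 36.2 CPM (1.92 ± 0.21, 0.00949). The others of the 10 largest fold changes, among calls with a mean of at least 20 counts and the same sign in every mutant library, were those of Zmynd10 (2.09 ± 0.34), a factor of motile cilia, Cyp4f39 (1.90), the dicarboxylate transporter Slc13a2 (1.75) with its overlapping partner Slc13a2os (1.86), BC055402 (1.74), the cell polarity gene Llgl2 (1.63) and the protease gene Adam33 (1.63). Also called were Aqp4, the water channel of astrocytes (1.27 ± 0.21, 32.1 to 77.8 CPM), the NMDA receptor subunit gene Grin2d (1.23 ± 0.19, 35.7 to 83.7 CPM), Twist2 (1.39), Trabd2b (1.17 ± 0.17) and Shroom3 (1.04). Aqp4 tended to be higher with a higher TSS share in wild-type mice of the other experiments as well. It had 33.5 CPM at 43.4% in Mecp2 control 2 and 110 CPM at 77.1% in R306C control 2. The cKO mice, at 58.4 to 103 CPM, lay between these, though Dnmt3a control 1 had 38.0 CPM at 63.4%. How far the share accounts for the rise of Aqp4 was not tested. Slc13a2 and Slc13a2os cannot be told apart, since the strand used in counting is not stated. The genes were not long: 3 of 46 spanned over 100 kb (6.52% against 15.1% of genes tested, Fisher's exact p = 0.145).

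Of 16413 gene bodies tested in the Dnmt3a cKO, 2751 had an unadjusted p under 0.05 (2029 higher and 722 lower), and DESeq2 called 472 higher and 13 lower, with 44 of the 46 among them. The lowest p among lower genes were those of 4930590L20Rik (−0.98, adjusted p = 0.0665) and Frmd3 (−0.75, 0.121), which did not pass, as did not Cntn6 (−0.68, 0.139), a cell adhesion gene. The count was 924 higher and 14 lower without control 1, 0 without control 2 or control 3, 3 without cKO 1, 60 without cKO 2 and 5 without cKO 3. It was 6 with the TSS to gene body ratio as a covariate, 14 with sex as a covariate and 19 among genes with a mean of at least 50 counts.

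**Figure D5:**
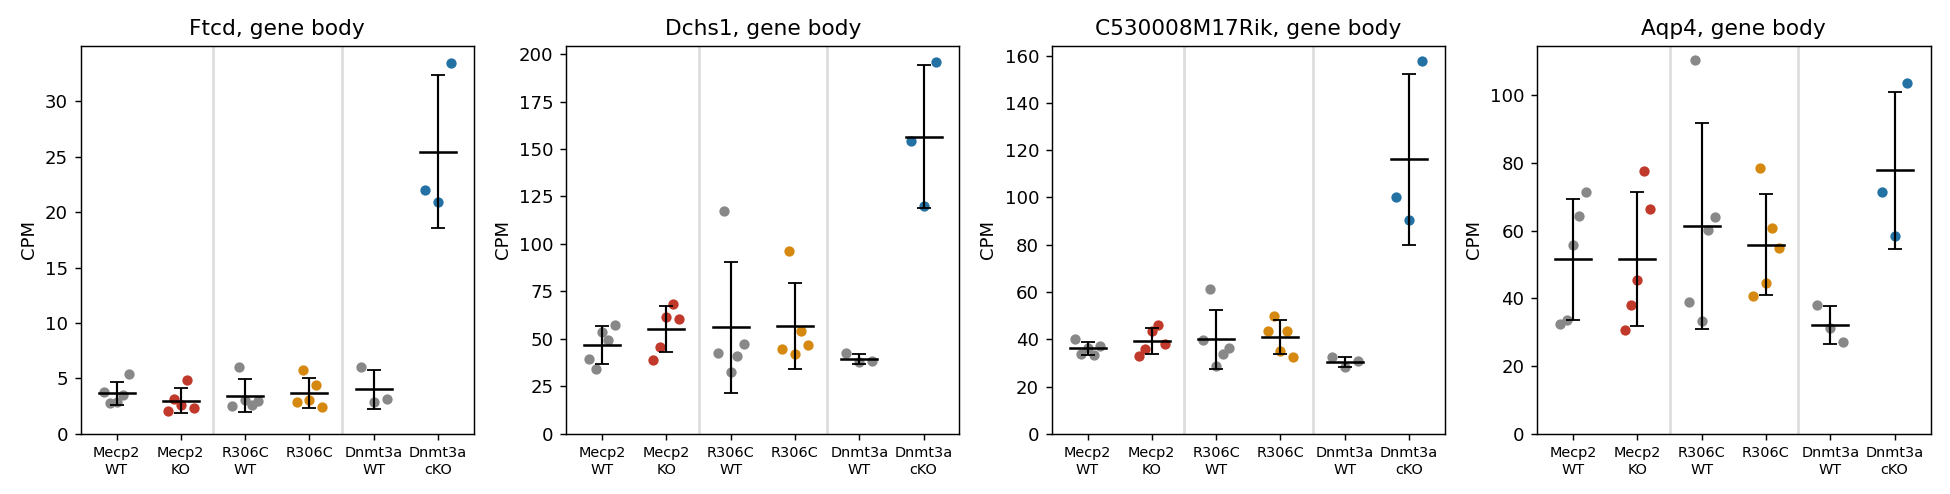
Gene body counts in CPM (vertical axes) of Ftcd, Dchs1, C530008M17Rik and Aqp4 in each library (points) of the 6 groups (horizontal axes), with the mean and SD as bars. In Dnmt3a cKO mice the means rose from 4.02 to 25.5 CPM for Ftcd and from 39.6 to 157 CPM for Dchs1.

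At the TSS of Dnmt3a cKO mice 8 genes rose and 1 fell. Crb2, a gene of epithelial polarity, rose from 2.82 ± 0.690 to 20.6 ± 3.16 CPM (SD, n = 3; log2 fold change 2.86 ± 0.25, adjusted p = 0.00259), and Myo5c, a myosin, from 4.62 to 23.4 CPM (2.35 ± 0.23, 0.00516). Dpys, an enzyme of pyrimidine breakdown (2.80 ± 0.40, 0.0417), BC016579 (2.79), Gm15179 (2.30), Speg (2.28), Lncenc1 (2.18) and Arsi (1.69) rose too. Trim71, a gene of early development, fell from 14.6 ± 1.21 to 4.26 ± 1.29 CPM (−1.77 ± 0.25, 0.0417). No gene was called in both windows. The gene body to TSS ratio rose for Dchs1 (log2 2.31 ± 0.25, adjusted p = 0.00949) and for the kinase gene Rps6ka4 (1.43 ± 0.19, 0.0255), and fell for Crb2 (−2.27 ± 0.27, 0.0152).

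At the TSS 14498 genes were tested in the Dnmt3a cKO, with 1109 at an unadjusted p under 0.05, and DESeq2 called 27 higher and 7 lower. Higher TSS calls numbered 4, 5 and 1 without control 1, 2 and 3, and 3, 2 and 10 without cKO 1, 2 and 3. Lower TSS calls, which Trim71 makes up with all libraries, numbered 3 without cKO 3 and 0 in the other omissions. The covariate left 1 higher TSS call and 0 lower, and without a low count filter 3 genes fell. Of 14103 ratios, 1658 had an unadjusted p under 0.05 and limma called 0. The ratio calls numbered 7 without control 1, 0 without control 2 or control 3, 1 without cKO 1 or cKO 2, and 7 without cKO 3.

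Immediate early genes, which answer neuronal activity, lay higher in gene bodies of Dnmt3a cKO mice (22 of 24 positive, median 0.48, camera adjusted p = 3.81e-06, and 0.188 with an estimated correlation). None rose over all genes and 8 rose adjusted over the list alone, among them Nr4a3 (0.92 ± 0.18), Fosl2 (0.83 ± 0.20), the neurotrophin gene Bdnf (0.71 ± 0.15) and Egr3 (0.71). At the TSS the same list had a median of −0.08 (adjusted p = 0.267). Astrocyte markers (18 of 20 positive, median 0.29, 0.000204 and 0.353 with an estimated correlation) had 1 member that rose, Aqp4, and 5 adjusted over the list alone, such as Ntsr2 (0.72) and Aldh1l1 (0.58). Excitatory neuron markers (21 of 24 positive, 0.27, 0.00101 and 0.188) had 6 adjusted over the list alone, among them the glutamate transporter gene Slc17a6 (0.99 ± 0.21) and the cortical transcription factor gene Emx1 (0.79), and none over all genes. None of the 11 gene body calls held with an estimated correlation. The others were axon guidance genes (0.16, 0.0107 and 0.188), oligodendrocyte markers (0.24, 0.0126 and 0.372), imprinted genes (0.20, 0.0150 and 0.353) and striatal markers (0.33, 0.0150 and 0.679) on the higher side. Oxidative phosphorylation genes (49 of 66 negative, −0.13, 0.0130 and 0.679), ribosomal protein genes (−0.16, 0.0168 and 0.679), heat shock genes (−0.25, 0.0485 and 0.679) and GABA receptors (−0.21, 0.0485 and 0.679) lay lower.

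Very long neuronal genes led the TSS lists of the Dnmt3a cKO (30 of 39 positive, median 0.23, camera adjusted p = 9.63e-06, and 0.294 with an estimated correlation), with the cell adhesion genes Cntn5 (0.60) and Ntm (0.53) as examples. Microglia markers lay lower (16 of 17 negative, median −0.49, 1.79e-05 and 0.488), with Tmem119 (−0.75) and Csf1r (−0.80) among them. Excitatory neuron markers lay higher (20 of 23 positive, 0.25, 3.22e-05 and 0.180). None of the 12 calls held with an estimated correlation, and no member of these 3 lists passed alone. The others were axon guidance genes (0.17, 0.00792), glutamate receptors (0.10, 0.0168), astrocyte markers (0.08, 0.0218), cadherins (0.12, 0.0346), genes over 100 kb (0.04, 0.0415), striatal markers (0.17, 0.0415), voltage-gated channels (0.08, 0.0415) and hippocampal markers (0.20, 0.0418) on the higher side, and vascular markers (−0.22, 0.0346) on the lower, with adjusted p of 0.294 to 0.529 for an estimated correlation.

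Fold changes correlated across genes between the Mecp2 KO and R306C at the TSS (r = 0.437, rho = 0.355, permutation p = 0.00794) and in gene bodies (r = 0.247, rho = 0.159, permutation p = 0.0159), with 0.0476 for each after adjustment over 6 correlations and 0.0625, the smallest possible, by exchange within pairs. Genes are not independent replicates, and 61.3% of them at the TSS and 53.1% in gene bodies had the same sign in both mutants. Below the real value, the highest absolute r of an arrangement was 0.387 at the TSS and 0.241 in gene bodies. In gene bodies another arrangement of the labels reached the real value, since the permutation p of 0.0159 exceeds the smallest possible, 0.00794. Among gene bodies with a mean of at least 50 counts the permutation p was 0.0476, and 0.125 within pairs. The 9 higher and 14 lower gene body genes of R306C mice differed in the Mecp2 KO by 1.07 in gene bodies and, with 8 and 12 of them tested, by 0.71 at the TSS (exact permutation p = 0.00794 for each, 0.0833 adjusted over 21 scores, and 0.0625 within pairs). The 116 higher and 68 lower genes of the Mecp2 KO differed in R306C mice by 0.35 in gene bodies and 0.25 at the TSS, where 101 and 59 were tested (exact permutation p = 0.317 and 0.0238, adjusted 0.417 and 0.167, and 0.0625 within pairs at the TSS).

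The Mecp2 KO and the Dnmt3a cKO had r = 0.551 in gene bodies and 0.327 at the TSS (rho = 0.568 and 0.210, permutation p = 0.167 and 0.381), and R306C and the Dnmt3a cKO 0.0257 and 0.159 (rho = −0.0460 and 0.0445, permutation p = 0.992 and 0.770). Gene body genes of the Mecp2 KO differed by 0.71 in gene bodies of Dnmt3a cKO mice, those of R306C by 0.75 and those of the joint fit by 0.71 (exact permutation p = 0.1 for each, the smallest possible). Of the 36 genes that rose in joint gene bodies, 32 of 35 tested were positive in Dnmt3a cKO gene bodies (median 0.43, 25 with an unadjusted p under 0.05), and Trabd2b was called in both. Of the lower ones, 15 of 20 tested were negative there (4 with an unadjusted p under 0.05). Of the joint TSS calls, 61 of 105 higher genes were positive at the Dnmt3a cKO TSS and 108 of 181 lower genes were negative. In Dnmt3a cKO gene bodies, which are another window, 72 of 105 of the higher genes were positive and 71 of 172 of the lower were negative. Among all Dnmt3a cKO gene bodies with an unadjusted p under 0.05, 2029 were higher and 722 lower. The 46 higher and only 2 lower genes of the Dnmt3a cKO differed by 0.50 in the Mecp2 KO and 0.19 in R306C mice (exact permutation p = 0.206 and 0.675), so that the lower side rests on 2 genes. Selected at an unadjusted p under 0.01, with 75 lower genes, the values were 0.42 and 0.07 (exact permutation p = 0.167 and 0.905).

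Differences between experiments passed their own test for few genes. Irak1 at the TSS was the only gene that differed between the Mecp2 KO and R306C (difference of log2 fold changes −1.88 ± 0.13, edgeR adjusted p = 8.75e-10), and 0 gene bodies did (83 at an unadjusted p under 0.05). Against the Dnmt3a cKO, C530008M17Rik (−1.82) and Ftcd (−2.97) differed in the gene body of the Mecp2 KO, and C530008M17Rik (−1.90) in that of R306C. At the TSS, 17 genes differed between the Mecp2 KO and the Dnmt3a cKO, among them Crb2 (−2.65), Irak1 (−1.78 ± 0.15) and Trim71 (1.81), and 11 between R306C and the Dnmt3a cKO. With blocks the counts against the Dnmt3a cKO were 16 and 38 in gene bodies, and 32 for the Mecp2 KO at the TSS. Those blocks also pair the Dnmt3a mice by replicate number, which did not meet the rule for pairs in that experiment.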

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

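The 3 tests on Irak1, that of detection power, that of a mechanism shared with Dnmt3a and the splits with the block were chosen only after the results were seen; those of the TSS share, of cKO 3 and of the other splits of the samples were set before their own values were computed, but after the joint fit and the Dnmt3a cKO calls had been seen.

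Irak1 TSS counts fell in the Mecp2 KO only. A loss of MeCP2 function shared with R306C does not explain this, since the log2 fold changes differed by −1.88. Composition or normalization does not either, since the fold change was −1.83 ± 0.10 with the TSS to gene body ratio as a covariate and −1.85 with DESeq2 size factors. A local effect of the knockout allele on the gene 2671 bp from Mecp2 stays open: Irak1 had 0.0287 ± 0.0939 in R306C and −0.09 ± 0.11 in the Dnmt3a cKO, and of 45 other genes tested within 1 Mb of Mecp2 the lowest adjusted p was 0.857 (edgeR).

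Long genes lay higher in the joint comparison of both Mecp2 mutants (TSS score difference 0.07 in the Mecp2 KO, and 0.01 in R306C, where alone it had an exact permutation p of 0.373). The TSS share of the libraries does not account for most of it: with its slope in control libraries removed, 73.5% of the TSS long gene score was kept (0.03, 8 of 10 pairs higher, exact permutation p = 0.0195). Greater detection power in long genes does not by itself give this direction, since 13.6% of the lower gene body calls spanned over 100 kb against 58.3% of the higher (Fisher's exact p = 0.000935). That test takes genes as independent units, which they are not, so its p does not measure the spread between mice. Cell type markers moved at the same TSS, with 18 of 18 microglia and 18 of 20 oligodendrocyte markers negative and 21 of 24 excitatory neuron markers positive in the joint fit, and a difference in cell makeup was not tested and stays open. Whether the change is shared with loss of Dnmt3a cannot be told apart, as the score of the joint calls in Dnmt3a cKO gene bodies had an exact permutation p of 0.1, the smallest that 3 mice per group allow.

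The 46 gene body calls of the Dnmt3a cKO were all higher. The TSS share may account for part of this: the slope of these genes on the share in the 10 control libraries of the other experiments (r = 0.970, exact permutation p = 6.94e-05, the smallest possible) predicts 26.2% of the difference of 1.31 for the share gap of 8.00 points, or 22.7% without the 2 libraries farthest from the median share. Cell makeup or dissection that varies with the share was not measured. Without cKO 3, 90.4% of the median log2 fold change of these genes was kept (1.32 against 1.19, with 46 of 46 above 0), while 5 of the 46 were still called. The genes were chosen on the same mice, so the kept median cannot exclude that cKO 3 contributed to the calls.

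Splits of the same samples into other groups of equal size gave these results. For the joint fit chance could be excluded only at the TSS, and only without adjustment over the split counts of all results. That fit was added after the data were seen. At the TSS only the real one of 100 splits gave 301 calls (highest other 3). In gene bodies 3 of 100 splits gave as many calls as the real 58 (highest other 2584), so that 2 other splits that part the pairs reached it. So few drawn splits do not place the share surely under 0.05, so chance could not be excluded there. It could not be excluded for the number of genes at the Mecp2 KO TSS (5 of 100, real 2, highest other 5261), which does not bear on Irak1 alone (edgeR adjusted p = 6.72e-06, and under 0.05 in all 10 omissions of a library); among the 16 splits that part all pairs, only the real one gave as many, and the highest other gave 0. Where 0 genes were called every split reaches that number, so the count says nothing about chance: this holds for gene bodies of the Mecp2 KO (100 of 100, highest other 5333) and R306C (100, 607), the TSS of R306C (100, 58) and the ratio in the Mecp2 KO (100, 5980) and R306C (100, 3). For the calls with the block, the 16 splits that part all pairs are too few for a share under 0.05: the real values and highest others were 11 and 2 at the R306C TSS, 4 and 0 at the Mecp2 KO TSS, and 2 and 0 for its ratio. With 0 real calls, another split called 1398 genes in R306C gene bodies with the block. Splits that call so many genes point to a structure of the samples other than genotype: the top split of Mecp2 KO gene bodies had a gap of 10.9 points in TSS share (real 5.51), that of the TSS and ratio 12.1, that of R306C gene bodies 11.4 (real 1.73) and that of the joint gene bodies 5.51 (real 3.62).

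The numbers of called lists were reached by other splits as well. This held for Mecp2 KO gene bodies (18 of 100, real 13, highest other 19; 4 of 16 splits that part all pairs) and TSS (10, real 11, highest 14; 5 of 16), R306C gene bodies (51, real 8, highest 20; 3 of 16) and TSS (75, real 2, highest 15; 14 of 16), and the joint fit in gene bodies (24, real 12, highest 20) and at the TSS (26, real 8, highest 17), so chance could not be excluded for any of these counts. The 10 splits of the Dnmt3a cKO experiment are too few for a share under 0.05. There, 1 split reached the real value in each case: 46 genes in gene bodies (highest other 0), 9 at the TSS (0), 3 ratios (0), 11 gene body lists (6) and 12 TSS lists (6).

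The numbers of genes with effects that differed between experiments were compared with 60 splits each, and chance could not be excluded for the numbers above 0. The difference of Irak1 itself between the Mecp2 KO and R306C had an edgeR adjusted p of 8.75e-10. For the Mecp2 KO against R306C 5 splits reached the real 1 at the TSS (highest other 1439), while in gene bodies the real number was 0, which all 60 reach by necessity (2). For the Mecp2 KO against the Dnmt3a cKO it was 10 for the real 2 in gene bodies (7) and 3 for the real 17 at the TSS (21). For R306C against the Dnmt3a cKO it was 14 for the real 1 in gene bodies (131) and 7 for the real 11 at the TSS (42).

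Of 220 groups of values, 18 held a library far from the others of its group, where about 1 in 20 would by chance. The share of TSS counts in the 10 top genes was 0.514% in KO 1 (others 0.406 to 0.419%). The share of gene body counts in the 10 top genes was 2.38% in R306C control 3 (1.42 to 1.66%) and 2.30% in R306C mutant 3 (1.44 to 1.62%). The TSS long gene score was −0.0924 in R306C mutant 4 (−0.06 to −0.05).

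Single genes with such a library were, in CPM with the range of the rest of the group: Twist2 gene body 6.92 in Mecp2 control 2 (8.86 to 9.46), Slc6a12 gene body 10.5 in the same mouse (14.0 to 15.1), Kcns1 TSS 20.1 in KO 2 (15.9 to 17.1), Pakap TSS 22.8 in KO 4 (26.8 to 28.3), Irak1 TSS 11.0 in KO 3 (14.5 to 15.1) and 3100003L05Rik TSS 8.27 in KO 3 (at most 2.91). In the gene bodies of the R306C experiment these were Fhdc1 14.0 (16.8 to 17.7) and Abca8a 8.43 (9.77 to 10.2) in mutant 1, and Fabp4 5.09 (1.62 to 2.47) and Gm11549 12.3 (15.4 to 16.6) in mutant 2. In its control 2 they were Dnmt3a 377 (281 to 307), Gm6498 52.9 (21.4 to 24.0), Cdh4 302 (153 to 184) and Stc2 27.1 (5.74 to 8.94).

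Between experiments the effects differed for 2 genes in gene bodies of the Mecp2 KO against the Dnmt3a cKO and 1 of R306C against it, and at the TSS for 1 gene of the Mecp2 KO against R306C, 17 against the Dnmt3a cKO and 11 of R306C against the Dnmt3a cKO.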

How the results depend on the processing

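The covariate, the joint fit, the omission of the R306C pair 2, selection with the block, differences of effects at the TSS and the block in the ratio fit were chosen only after results were seen; the other settings were fixed before. The counts per gene leave the window limits, the strand and any scaling of the libraries unstated, the Dnmt3a cKO has 3 mice per group, and Mecp2 KO, R306C and Dnmt3a cKO mice were compared across separate experiments. Counts of calls moved with tool and setting, and the cause was not tested.

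By the DESeq2 Wald test the calls were 72 higher and 1 lower in Mecp2 KO gene bodies, 15 and 11 at its TSS, and 1 and 6 at the R306C TSS. In the Dnmt3a cKO they were 472 and 13 in gene bodies and 27 and 7 at the TSS. The joint fit gave 148 and 71 in gene bodies and 216 and 270 at the TSS. With the TSS to gene body ratio as a covariate, 2 genes were higher and 2 lower at the Mecp2 KO TSS. Dnmt3a cKO calls were then 6 higher in gene bodies, and 1 higher and 0 lower at the TSS. Joint calls with the covariate were 49 and 85 in gene bodies, and 26 and 78 at the TSS. The joint covariate fit had no replicate block, so the joint fit without the block is its reference.

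With the replicate block, 4 genes were lower at the Mecp2 KO TSS, 1 higher and 10 lower at the R306C TSS, and 2 ratios higher in the Mecp2 KO; the joint fit without it called 3 and 1 in gene bodies and 5 and 15 at the TSS. In the Dnmt3a cKO the replicate numbers did not meet the rule for pairs: same-numbered samples correlated at −0.03 to 0.30 in gene bodies and 0.07 to 0.21 at the TSS, and 2 and 5 of 6 samples correlated best with their own number. The replicate block there gave 4 higher gene bodies, 2 higher and 0 lower TSS, 0 changed ratios, and ended the calls of GABA receptors and heat shock genes (adjusted p = 0.0586 each, gene body) and hippocampal markers (0.0627, TSS). It changed no list call beyond these and those given with the Mecp2 KO and R306C lists. Differences of effects with blocks numbered 16 (Mecp2 KO) and 38 (R306C) against the Dnmt3a cKO in gene bodies and 32 for the Mecp2 KO at the TSS.

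Other settings gave 19 higher Dnmt3a cKO gene bodies with a mean of at least 50 counts, 14 with sex as a covariate, 1 lower without a low count filter (3 lower at the TSS), and 0 ratios by limma. Without the R306C pair 2 the joint gene body calls were 181 and 62. With an estimated correlation the called lists went from 13 to 0 (Mecp2 KO gene body), 11 to 2 (its TSS), 8 to 0 (R306C gene body), 2 to 1 (its TSS), 11 to 0 and 12 to 0 (Dnmt3a cKO), and 12 to 0 and 8 to 1 (joint).

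The long gene score was −0.0608 in Mecp2 KO gene bodies with matched shorter genes, 0.0671 at its TSS with the replicate block (exact permutation p = 0.0625) and 0.00695 for its gene body minus TSS with medians (−0.201 with matched genes). In R306C it was −0.0114 at the TSS with medians and −0.0126 for gene body minus TSS with matched genes, and in the Dnmt3a cKO 0.00909 for gene body minus TSS with medians and −0.307 with matched genes. Its gene body score was −0.149 with matched genes, −0.0223 with the 60 kb limit and −0.0185 with medians (exact permutation p = 0.1 each, the smallest possible), and its TSS score was 0.105 with the 200 kb limit (exact permutation p = 0.1). In R306C gene bodies the matched score was 0.00988. Scores across experiments with the replicate block were 0.25 for Mecp2 KO genes at the R306C TSS, and 1.07 and 0.71 for R306C genes in Mecp2 KO gene bodies and TSS (exact permutation p = 0.0625 each). With genes selected with the replicate block, R306C genes scored −0.10 in the Dnmt3a cKO gene body minus TSS, and Dnmt3a cKO genes 0.0734 at the R306C TSS (exact permutation p = 0.0159) and −0.0168 in its gene body minus TSS. At an unadjusted p under 0.01, Dnmt3a cKO genes scored 0.0864 at the Mecp2 KO TSS (exact permutation p = 0.0317) and −0.0211 in the R306C gene body minus TSS. The correlation of R306C and the Dnmt3a cKO in gene bodies was −0.00675 with a mean of at least 50 counts.

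Named genes whose small log2 fold change reversed were Dnmt3a in Mecp2 KO gene bodies (−0.00158 with the replicate block), Dnmt3a at its TSS (0.12 with the covariate), Irak1 R306C gene body counts (−0.0446 without pair 2), Mecp2 R306C gene body counts (−0.0306 without pair 2), Dnmt3a R306C TSS counts (−0.000692 without pair 2), Irak1 in Dnmt3a cKO gene bodies (0.18 with the covariate), and Mecp2 in joint gene bodies (0.0144), Dnmt3a (0.0254) and Mirg (0.0454) at the joint TSS with the covariate.

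With each library omitted in turn, the lowest and highest values were: higher and lower calls 0 to 1 higher in Mecp2 KO gene bodies, 1 to 2 lower at its TSS, 0 to 924 and 0 to 14 in Dnmt3a cKO gene bodies, 1 to 10 and 0 to 3 at its TSS, 0 to 7 ratios, 11 to 136 and 5 to 58 in joint gene bodies, and 25 to 101 and 72 to 172 at the joint TSS. The long gene score ran from −0.0143 to 0.0743 (gene body), 0.0563 to 0.0790 (TSS) and −0.0882 to 0.0171 (difference) in the Mecp2 KO, −0.0236 to 0.0716, 0.00331 to 0.0264 and −0.0373 to 0.0699 in R306C, and −0.0162 to −0.00172, 0.0396 to 0.0784 and −0.0695 to −0.0285 in the Dnmt3a cKO. Genes that changed sign ran from −0.0337 to 0.0353 (Dnmt3a) in Mecp2 KO gene bodies, −0.10 to 0.0665 (Dnmt3a) at its TSS, −0.10 to 0.0854 (Irak1) and −0.0930 to 0.0886 (Mecp2) in R306C gene bodies, −0.0383 to 0.0451 (Dnmt3a), −0.0228 to 0.0808 (Irak1) and −0.0698 to 0.00148 (Mecp2) at its TSS, −0.35 to 0.00521 (Irak1) in Dnmt3a cKO gene bodies, and −0.0255 to 0.0123 (Dnmt3a) and −0.00439 to 0.0362 (Mecp2) at the joint TSS. Of all named gene values 4464 stayed the same in these omissions, 73 were stronger, 430 weaker and 32 reversed; under the other settings 2360 stayed the same, 127 were stronger, 121 weaker and 9 reversed.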

Other observations

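The hypotheses below, and the choice of genes shared between experiments, were made only after the results were seen.

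The remaining joint gene body calls were immediate early genes (22 of 25 positive, median 0.12, camera adjusted p = 0.00143, and 0.562 with an estimated correlation), oligodendrocyte markers (18 of 20 negative, −0.10, 0.0036 and 0.665), striatal markers (11 of 13 positive, 0.15, 0.00502 and 0.648), genes over 100 kb (1516 of 2478 positive, 0.03, 0.00596 and 0.665), voltage-gated channels (0.05, 0.0168 and 0.665) and very long neuronal genes (0.03, 0.0281 and 0.829). Cadherins did not pass (adjusted p = 0.0522), though Cdh4 and Cdh6 rose in joint gene bodies, and Cdh12 (0.45) and Cdh18 (0.21) at the TSS. Single members that changed at the joint TSS included the imprinted genes Plagl1 (0.29) and Snrpn (0.42), Oprk1 (−0.32), Gabrg1 (−0.35), the glutamate receptor gene Grin3a (−0.31), Robo3 (−0.61) and the calcium channel gene Cacna1g (−0.29). The widely discussed MeCP2 targets moved as a group in no experiment: the adjusted p was 0.649 and 0.537 in the Mecp2 KO (gene body and TSS), 0.894 and 0.693 in R306C, 0.292 and 0.356 in the Dnmt3a cKO, and 0.482 and 0.774 in the joint fit. In the Mecp2 KO TSS they had a median of 0.04 and a mean of −0.10, since Irak1 is a member.

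Of the other lists, inhibitory neuron markers had medians of 0.03 and 0.05 in the Mecp2 KO (gene body and TSS, adjusted p = 0.649 and 0.545), −0.01 and −0.09 in R306C (0.881 and 0.239) and 0.24 and 0.06 in the Dnmt3a cKO (0.152 and 0.618). Glutamate receptors had −0.01 and 0.05 in the Mecp2 KO (0.678 and 0.143) and −0.09 in Dnmt3a cKO gene bodies with a mean of 0.04 (0.848), where Grin2d rose. Thalamic markers had 0.13 and −0.06 in the Mecp2 KO (0.649 and 0.344) and −0.13 and −0.07 in R306C (0.355 and 0.177), and hippocampal markers −0.07 and −0.07 in the Mecp2 KO (0.649 and 0.136). Hox genes, with 4 members, had 0.14 in Mecp2 KO gene bodies (0.200). Ribosomal protein genes had −0.06 and 0.03 in the Mecp2 KO (0.111 and 0.344) and oxidative phosphorylation genes −0.05 and −0.01 (0.146 and 0.937). At the R306C TSS microglia markers (−0.11, 0.107) and oligodendrocyte markers (−0.09, 0.105) did not pass. Medians and means, or the test, differed in sign only in lists that were not called, such as imprinted genes at the Mecp2 KO TSS (0.02 and −0.00) and cadherins in Dnmt3a cKO gene bodies (−0.07 and 0.02).

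A hypothesis is that MeCP2 limits transcription of long genes at initiation. The joint TSS score kept 73.5% of its size with the TSS share removed, but R306C alone had a difference of 0.01 (exact permutation p = 0.373). The gene body minus TSS score (−0.01 ± 0.08, SD, 10 pairs) was too variable to place a TSS difference of 0.04 before or within the gene body. Microglia and oligodendrocyte markers lay lower and excitatory neuron markers higher at the same TSS, so that cell makeup stays open as well. Counting initiation events with a method of capped nascent RNA, and comparing genes by measured DNA methylation, would test it.

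A hypothesis is that lower TSS counts of oligodendrocyte precursor markers in both mutants come from fewer such cells or from less transcription per cell. The list kept its call with an estimated correlation (adjusted p = 0.00585). Counts of labelled cells, or nuclei sorted by type, would tell these apart.

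A hypothesis is that Irak1 might lose TSS counts through the knockout allele itself. Irak1 had 0.0287 in R306C, which leaves this open. A second Mecp2 null allele with a different deletion would test it.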
